A study of Mus musculus with 12 samples.

How the data were processed

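Polyadenylated RNA from 12 libraries of 2 mouse cell lines was sequenced with a stranded kit, per the labels. Both lines carry the cell type label mesenchymal stem cells. The labels describe infection with a lentivirus carrying Rik or an empty vector, at a higher virus titre and in another medium for MK3 than for MPTC, puromycin selection and the use of cloned lines. The authors deposited counts per gene and FPKM per gene, each with 12 sample columns. The submitters' notes name Trimmomatic, HISAT2, Cufflinks, HTSeq and DESeq and the build GRCm39, without their roles, and versions are not given in the sources used here. The ratio of count over column total to FPKM was constant between libraries for each gene, to a largest relative deviation of 6.16e-07, so both deposited tables hold the same measurements.

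Total counts per library were 1.69e+07 to 2.01e+07, and counts were analysed as deposited. Genes were kept by filterByExpr, which left 12683 of 17433, and TMM factors scaled the libraries. The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with a mean for each of the 4 groups, all 12 libraries in 1 fit and a Benjamini-Hochberg adjusted p under 0.05 as the threshold for a called gene. The contrasts were Rik minus empty vector in each line, the difference of these effects, and MPTC minus MK3 controls. Standard errors of log2 fold changes were derived from the F statistic and are approximate. Group levels of single genes are TMM-scaled CPM, whereas levels given for single libraries use the library total.

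Before the data were examined, 36 gene lists were written, of which 34 had at least 5 tested members. Distal nephron and collecting duct genes (4 tested) and mitochondrially encoded genes (0 in the table) were not tested as lists. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, with adjusted p over the lists of each contrast. A rule for the genes to be named was written at the same time. It took Rik first. In each line it took the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM, no overlap between the groups and a symbol that is not a predicted-gene or clone name. It took the 4 members of smallest p in the Wnt target, Wnt component and nephron progenitor lists, and the 3 of smallest p in the called direction in up to 5 other called lists. Across lines it took up to 4 genes changed alike in each direction and 4 changed in opposite directions, for which 0 genes qualified. Between control lines it took 3 members each of the nephron progenitor, proximal tubule, epithelial and extracellular matrix lists. Of the genes the rule took, 1 is not reported here.

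Alternatives were median-ratio scaling, DESeq2 1.42.0, no filter on low counts, a filter of 1 CPM in 3 libraries, each line fitted alone, replicate number as a block, each library left out, an absolute log2 fold change over 1, and limma on log2(FPKM + 1) or log2(FPKM + 0.1) with a filter of 1 FPKM in 3 libraries or, for the first, none. After the data were seen, fits without MPTC control replicates 2 and 3 and without genes that MK3 RNA could shift by over 5% were added. The procedure was tested on simulated counts: edgeR called 76% of 50 genes changed 1.25-fold in MPTC and all 50 changed 4-fold, with 13 false calls among 194. In MK3 it called 70% of 50 changed 1.25-fold, 94% of 50 others changed 1.5-fold and 96% of 50 others changed 2-fold. The changed genes were drawn above a minimum level, and simulated libraries of a group shared the same mean for each gene. A shift of many genes in some libraries of a group was not simulated, so these rates may not hold for the real libraries. Chromosomes were assigned by symbol from a GRCm38 gene table, which matched 12650 of the tested genes, and no coordinates are given because the build differs. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.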

Results

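RNA was sequenced from 2 mouse cell lines, MPTC and MK3, after lentiviral overexpression of the long noncoding RNA 4933425B07Rik, called Rik below. Each line had 3 libraries from Rik-infected cells and 3 from cells infected with an empty vector, the controls, so that 12 libraries fell into 4 groups. Total counts per library ranged from 1.69e+07 to 2.01e+07 over 17433 genes. The labels number the libraries of each group as biological replicates and do not say whether they came from separate infections, so the p-values measure the spread between these libraries. The study's title names renal hypoplasia and the Wnt/β-catenin pathway, and the comparison of Rik with empty vector in each line asks which genes change with Rik. Rik itself had 0 rows in the count table, so its level is not analysed here.

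In MPTC cells, genes known to respond to interferon were higher in the Rik libraries. Of 43 tested interferon-stimulated genes, 42 rose and 0 fell, with a median log2 fold change of 0.56 (camera adjusted p = 7.56e-114, and adjusted p = 0.00714 with an estimated correlation). Oas2, an antiviral oligoadenylate synthetase, rose from 90.0 ± 5.45 to 190.2 ± 7.84 CPM, counts scaled to a common library size (mean ± SD, n = 3 libraries). Ifi44, an interferon-induced gene, rose from 75.7 ± 4.92 to 181 ± 16.7 CPM, and Dhx58, a regulator of cytosolic RNA sensing, rose from 38.3 ± 2.85 to 83.5 ± 6.15 CPM. Their log2 fold changes were 1.08 (SE 0.05), 1.26 (SE 0.06) and 1.13 (SE 0.06), with edgeR adjusted p of 1.39e-11, 3.88e-11 and 6.56e-10. For 42 of the 43 genes the 3 Rik libraries did not overlap the 3 controls. Adjusted over the list alone, 42 were higher and 0 lower.

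**Figure D1:**
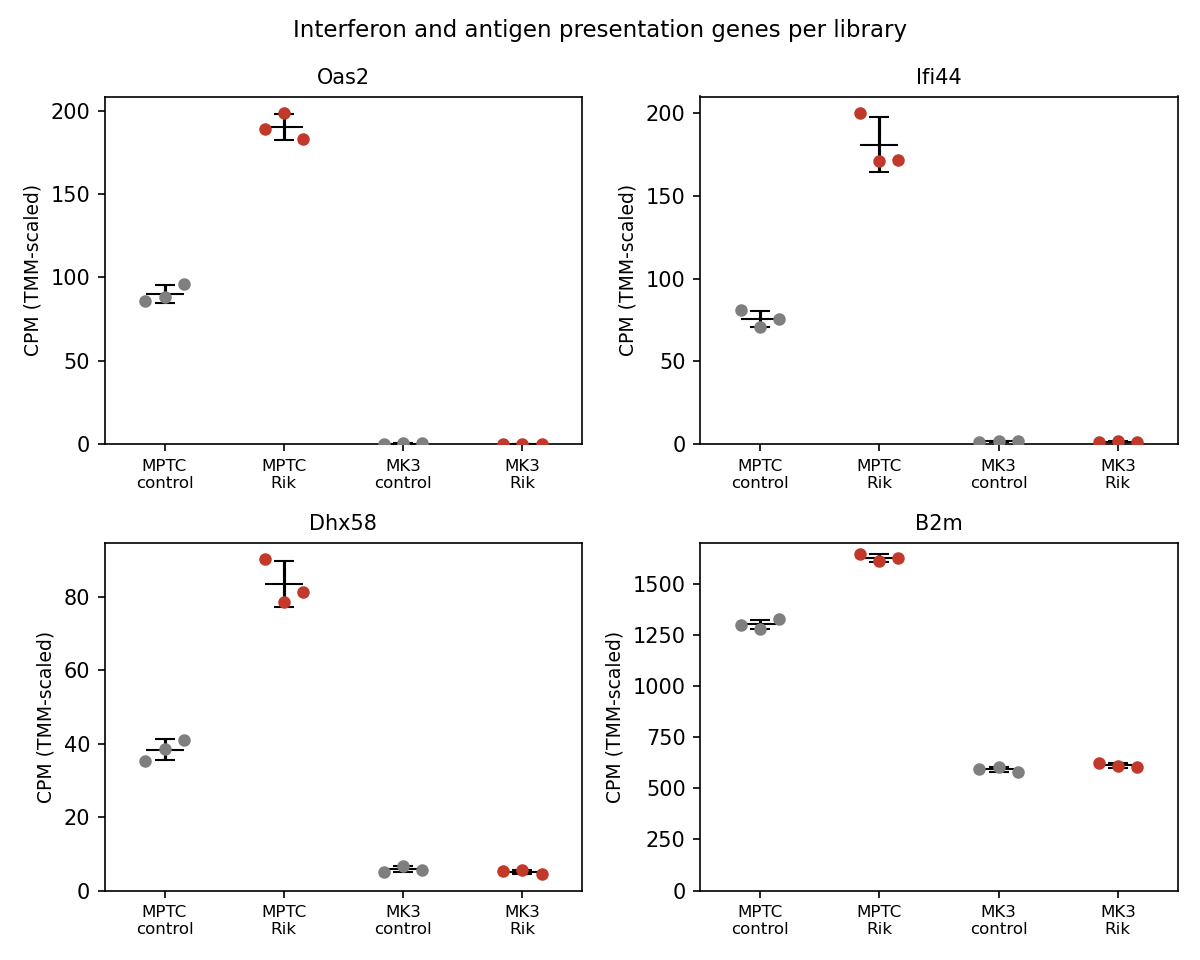
Levels of Oas2, Ifi44, Dhx58 and B2m in TMM-scaled CPM (vertical axis) in the 4 groups; points are libraries, the long bar is the group mean and the whiskers are ± SD. In MPTC the 3 Rik libraries lay above the 3 controls for each gene, with mean Oas2 levels of 90.0 and 190.2 CPM.

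Genes of antigen presentation, inflammation and the p53 response were also higher in MPTC Rik libraries. In the MHC class I list, 12 of 18 members rose and 2 fell (camera adjusted p = 2.52e-12, and adjusted p = 0.074 with an estimated correlation). H2-K1, a class I heavy chain, rose from 1337 ± 54.0 to 1787 ± 45.0 CPM, B2m, the class I light chain, from 1303 ± 23.2 to 1629 ± 18.5 CPM, and Nlrc5, a transactivator of class I genes, from 89.7 ± 3.83 to 128 ± 10.1 CPM (mean ± SD, n = 3). In the NF-κB inflammatory list, 17 of 33 members rose and 0 fell (camera adjusted p = 3.77e-11, and adjusted p = 0.0229 with an estimated correlation). The chemokine Cxcl1 had a log2 fold change of 0.77 (SE 0.06), the cytokine Lif one of 0.84 (SE 0.07) and the chemokine Ccl5 one of 0.96 (SE 0.11). Of 28 p53 targets, 14 rose and 1 fell (camera adjusted p = 3.97e-08, and adjusted p = 0.0399 with an estimated correlation). Adjusted over the list alone, 13, 18 and 15 members of the respective lists were higher and 2, 2 and 2 lower. Leukocyte and macrophage markers moved in the same comparison: 2 of 12 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.00338, and adjusted p = 0.673 with an estimated correlation). Their summed level was 116, 43.1 and 37.6 CPM in control replicates 1, 2 and 3 and 103, 106 and 107 CPM in the Rik libraries. The median log2 fold change of the markers was 1.00, and 4.16, 0.50 and 0.48 without control replicates 1, 2 and 3 in turn. Without control replicates 2 and 3 together, a choice made after seeing the data that leaves 1 control library, the marker median was -0.32. The MHC class I, NF-κB and p53 medians were then 0.34, 0.24 and 0.23, against 0.30, 0.32 and 0.21 with all libraries. Whether macrophage RNA gave part of the NF-κB rise was not tested.

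ERK target genes rose and mitotic genes fell in MPTC cells by the preset correlation. Of 26 ERK targets, 18 rose and 2 fell (camera adjusted p = 9.19e-09, and adjusted p = 0.0774 with an estimated correlation). The ERK phosphatase Dusp6 had a log2 fold change of 0.57 (SE 0.05), the immediate early gene Ier3 one of 0.50 (SE 0.06) and the transcription factor Myc one of 0.56 (SE 0.08). Of 36 genes of the G2 and M phases, 19 fell and 1 rose (camera adjusted p = 9.19e-09, and adjusted p = 0.0774 with an estimated correlation). The spindle checkpoint kinase Bub1b fell by 0.32 (SE 0.04) on the log2 scale, the ubiquitin-conjugating enzyme Ube2c fell by 0.31 (SE 0.04) and the spindle protein Tacc3 fell by 0.21 (SE 0.03). Ribosomal protein genes had 17 of 44 members lower and 0 higher (camera adjusted p = 6.10e-07, and adjusted p = 0.71 with an estimated correlation). Extracellular matrix genes had 15 of 33 lower and 1 higher (camera adjusted p = 3.07e-05, and adjusted p = 0.201 with an estimated correlation). Adjusted over the list alone, the higher and lower members were 18 and 3 for ERK, 1 and 23 for G2 and M, 1 and 24 for ribosomal and 2 and 17 for matrix genes. Without control replicates 2 and 3, a choice made after seeing the data, the ribosomal and matrix lists had medians of -0.02 and -0.04. With all libraries these were -0.10 and -0.17. The ERK and G2 and M medians were 0.24 and -0.10 without those replicates, against 0.24 and -0.11 with all libraries. The matrix gene Col3a1 stood at 5.36 and 6.53 CPM in those replicates and at 0 CPM in the other 4 MPTC libraries.

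Wnt target genes were not called as a group by camera in MPTC cells. The mixed test of fry, for changes in either direction, passed for these targets (adjusted p = 1.01e-04). It also passed for the pathway components (adjusted p = 4.61e-08) and for most lists in MPTC. Of 23 tested targets, 4 rose, 1 fell and 18 were not called (camera adjusted p = 0.594, and adjusted p = 0.74 with an estimated correlation), and the median (-0.02) and mean (-0.24) log2 fold changes differed in sign from the test's direction, up. Myc rose from 103 ± 10.1 to 152 ± 21.7 CPM (mean ± SD, n = 3), the AP-1 gene Fosl1 and the matricellular gene Ccn4 had log2 fold changes of 0.24 (SE 0.04) and 0.20 (SE 0.05), and the cyclin Ccnd1 had -0.16 (SE 0.04). Among 47 pathway components, 7 rose and 5 fell (camera adjusted p = 0.973, and adjusted p = 0.979 with an estimated correlation; median -0.01, test direction up). The receptors Fzd6 and Fzd5 had log2 fold changes of 0.28 (SE 0.03) and 0.37 (SE 0.09) and the kinase Gsk3b 0.22 (SE 0.04). Ctnnb1, which encodes β-catenin, went from 415 ± 13.1 to 369.5 ± 13.3 CPM (-0.17, SE 0.03 on the log2 scale, edgeR adjusted p = 0.0013). Adjusted over the list alone, 4 targets and 7 components were higher and 1 and 5 lower. Without control replicates 2 and 3, which leaves 1 control library, Fzd6 was called at 0.25, while Myc (0.41), Fosl1 (0.20), Ccnd1 (-0.17), Ccn4 (0.13), Fzd5 (0.29), Gsk3b (0.13) and Ctnnb1 (-0.12) were not. Ccn4 was also not called without control replicate 2 (0.16) or Rik replicate 1 (0.14).

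Among nephron progenitor and induction genes in MPTC cells, 2 of 18 rose and 1 fell (camera adjusted p = 0.866, and adjusted p = 0.899 with an estimated correlation). Traf1, an adaptor of TNF receptor signalling, had a log2 fold change of 0.43 (SE 0.06), the nephric transcription factor Pax8 one of 0.26 (SE 0.05) and the zinc-finger factor Sall1 one of -0.16 (SE 0.05). Hoxa11 averaged 0.15 CPM in controls, was at 0 in the Rik libraries and was not called (edgeR adjusted p = 0.0539). It passed without control replicate 1, control replicate 3 or MK3 Rik replicate 1. Its log2 fold change was -5.17 without control replicate 1 and -2.32 without control replicate 2. Hoxa11 stood at 41.6 CPM in MK3 controls and is among the genes that a small share of MK3 RNA could shift. Adjusted over the list alone, 2 members were higher and 3 lower. Pax8 (0.19) and Sall1 (-0.20) were not called without control replicates 2 and 3, nor was Sall1 without Rik replicate 1 (-0.14).

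The genes with the largest changes under the naming rule were mostly of low abundance in MPTC cells. Fbln1, a matrix glycoprotein, rose from 5.14 ± 0.388 to 15.6 ± 1.23 CPM (mean ± SD, n = 3), a log2 fold change of 1.59 (SE 0.09). It was followed by Cxcl2 (1.40, SE 0.36), Ifit3b (1.31, SE 0.15), Ifi44, Slfn2 (1.23, SE 0.30) and Gramd1b (1.17, SE 0.17). The falls were Ptprn (-1.01, SE 0.16), the smooth muscle gene Tagln (-0.98, SE 0.17), the keratin Krt19 (-0.95, SE 0.13), Ccbe1 (-0.79, SE 0.11), the immune receptor Tigit (-0.78, SE 0.14) and the carbonyl reductase Cbr3 (-0.76, SE 0.14). Without control replicates 2 and 3, Cxcl2 (0.24), Slfn2 (0.38), Gramd1b (0.64) and Ptprn (-0.50) were not called, and the log2 fold change of Tagln in MPTC was then -0.83, also not called, while the log2 fold change of Krt19 in MPTC was -0.58 and still called. Without control replicate 1, Cxcl2 had 2.75 and Slfn2 1.94. Cxcl2 stood at 29.9, 4.90 and 5.47 CPM in control replicates 1, 2 and 3 and at 34.2 to 37.1 CPM in the Rik libraries, per library total. Krt8, a keratin abundant in MK3, stood at 0.66, 5.87 and 6.58 CPM in these controls and at 0.516 to 0.711 CPM in the Rik libraries.

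**Figure D2:**
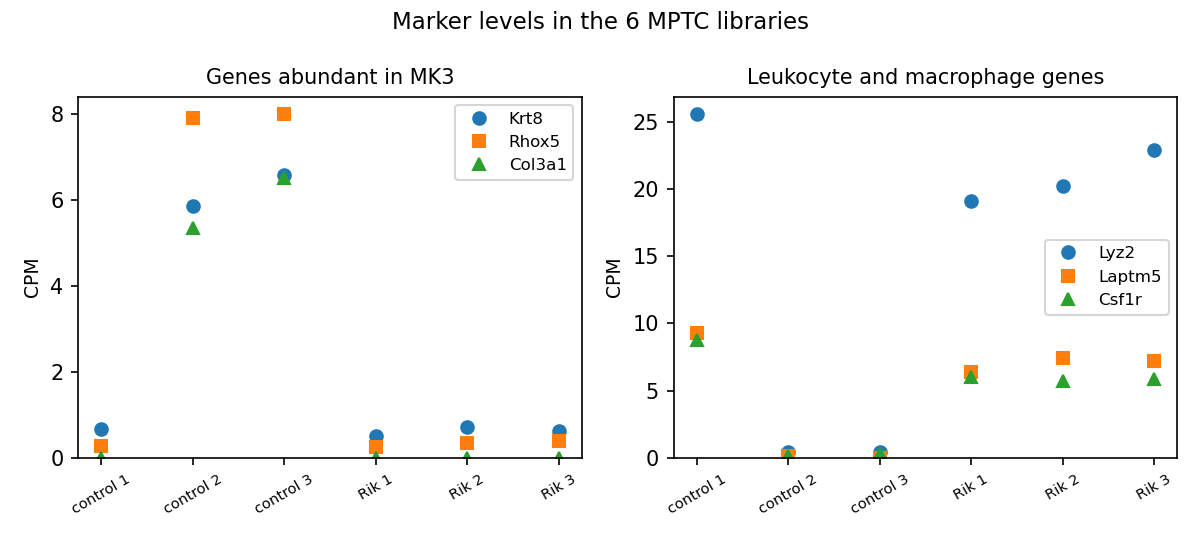
Levels in CPM (vertical axes) of 3 genes abundant in MK3 (left) and 3 leukocyte and macrophage genes (right) in each of the 6 MPTC libraries (horizontal axes); each point is 1 library. Krt8 lay at 5.87 and 6.58 CPM in control replicates 2 and 3 and at most 0.711 CPM in the others, and Lyz2 at 0.408 and 0.442 CPM in those replicates and 25.6 CPM in control replicate 1.

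Over all 12683 genes tested in MPTC cells, 1268 were higher and 1392 lower in Rik libraries by the edgeR quasi-likelihood test. The median absolute log2 fold change of called genes was 0.21, and 51 higher and 70 lower genes had an absolute log2 fold change over 1. The groups did not overlap for 35.7% of genes, against 10% by chance. The first principal component of the MPTC libraries, with 68.0% of the variance, mainly set control replicates 2 and 3 apart from the other libraries. Control replicate 1 stood at -14.9 on it and the Rik libraries at -18.0 to -17.2. Control replicates 2 and 3 stood at 33.6 and 34.6. Without control replicate 2 the counts were 757 and 870, and without Rik replicate 1 there were 774 higher genes. Without control replicates 2 and 3 they were 238 and 170.

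In MK3 cells, edgeR called 0 higher and 0 lower genes with Rik. The smallest adjusted p was 0.414, 777 genes had an unadjusted p under 0.05 against 634 by chance, and the groups did not overlap for 11.8% of genes against 10% by chance. DESeq2 called 5 genes: Sesn2, a stress-induced sestrin, and Aldh1a1 as higher, and Sparc, Ly6e and Ppp1r10 as lower, of which all but Sesn2 were named after their values were seen. Sesn2 stood at 33.7 ± 1.63 CPM in controls and 42.9 ± 6.87 CPM in Rik libraries (mean ± SD, n = 3; log2 fold change 0.35, SE 0.08, edgeR adjusted p = 0.414; 0.21 without Rik replicate 2). Limma on log2(FPKM + 1) called 0 genes with its filter and 2 higher and 2 lower without it, and edgeR without Rik replicate 1 called 1 gene, Srp54b.

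The Wnt and nephron lists had 0 called members in MK3 cells, also adjusted over the list alone. For the Wnt targets the median log2 fold change was -0.04 (camera adjusted p = 0.332, and adjusted p = 0.825 with an estimated correlation). Ccnd1 stood at 325 ± 16.0 CPM in controls and 302 ± 4.94 CPM in Rik libraries (mean ± SD, n = 3). The log2 fold changes of Sox9 and Ccn4 were 0.18 (SE 0.07) and -0.17 (SE 0.07), and Nrcam was at 0.055 ± 0.055 and 0.861 ± 1.40 CPM in control and Rik libraries, a log2 fold change of 3.84 that was 0.02 without Rik replicate 1. For the components (median 0.00, test direction down; camera adjusted p = 0.88, and adjusted p = 0.908 with an estimated correlation) the values were 0.30 (SE 0.13) for Fzd3, -0.16 (SE 0.07) for Tle4, -0.08 (SE 0.04) for Fzd6 and 0.07 (SE 0.04) for Dvl2. For the nephron list (median 0.03, test direction down; camera adjusted p = 0.76, and adjusted p = 0.875 with an estimated correlation) Traf1 had -0.15 (SE 0.06), while Osr1 and Pax2 stood at 0.251 and 0.301 CPM in controls and 0.435 and 0.163 CPM in Rik libraries. Without Rik replicate 1, Sox9 had 0.12 and the nephron median was -0.04, and without Rik replicate 2 that median was 0.15, with Tle4 at -0.10 and Dvl2 at 0.04. Ccn4 had -0.11 without control replicate 1.

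With the preset correlation, camera called 4 lists in MK3 cells, all by small shifts. Ribosomal proteins had a median log2 fold change of 0.04 (camera adjusted p = 5.12e-05, and adjusted p = 0.825 with an estimated correlation), with Rpl27 at 0.08 (SE 0.03), Rpl18 at 0.10 (SE 0.04) and Rplp0 at 0.08 (SE 0.04). Genes of integrated and endoplasmic reticulum stress had 0.02 (camera adjusted p = 0.00117, and adjusted p = 0.716 with an estimated correlation), with Sesn2, Chac1 at 0.42 (SE 0.11) and Herpud1 at 0.21 (SE 0.06). Genes of the G2 and M phases had -0.02 (camera adjusted p = 0.00904, and adjusted p = 0.825 with an estimated correlation), with Kif23 at -0.08 (SE 0.04), Tacc3 at -0.06 (SE 0.03) and Cenpe at -0.06 (SE 0.04). Nuclear oxidative phosphorylation genes had 0.02 (camera adjusted p = 0.0168, and adjusted p = 0.825 with an estimated correlation), with Cox7c at 0.11 (SE 0.04), Ndufa4 at 0.10 (SE 0.04) and Cox4i1 at 0.09 (SE 0.04). Without control replicate 1 the ribosomal median was 0.03, and without Rik replicate 3 the G2 and M median was -0.04, with Cenpe at -0.10. Without Rik replicate 2, Sesn2 had 0.21, Chac1 0.23 and Herpud1 0.11. In these 4 lists 0 members were called over all genes tested, and adjusted over the list alone 4 stress genes and 0 others were higher. The G2 and M list was not called without control replicate 2 or Rik replicate 2, the stress list without Rik replicate 2, and the oxidative phosphorylation list without control replicate 1, Rik replicate 2 or Rik replicate 3. MK3 Rik replicate 1 stood apart, with 15325 genes detected against 13860 to 14084 in the other 5 MK3 libraries.

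**Figure D3:**
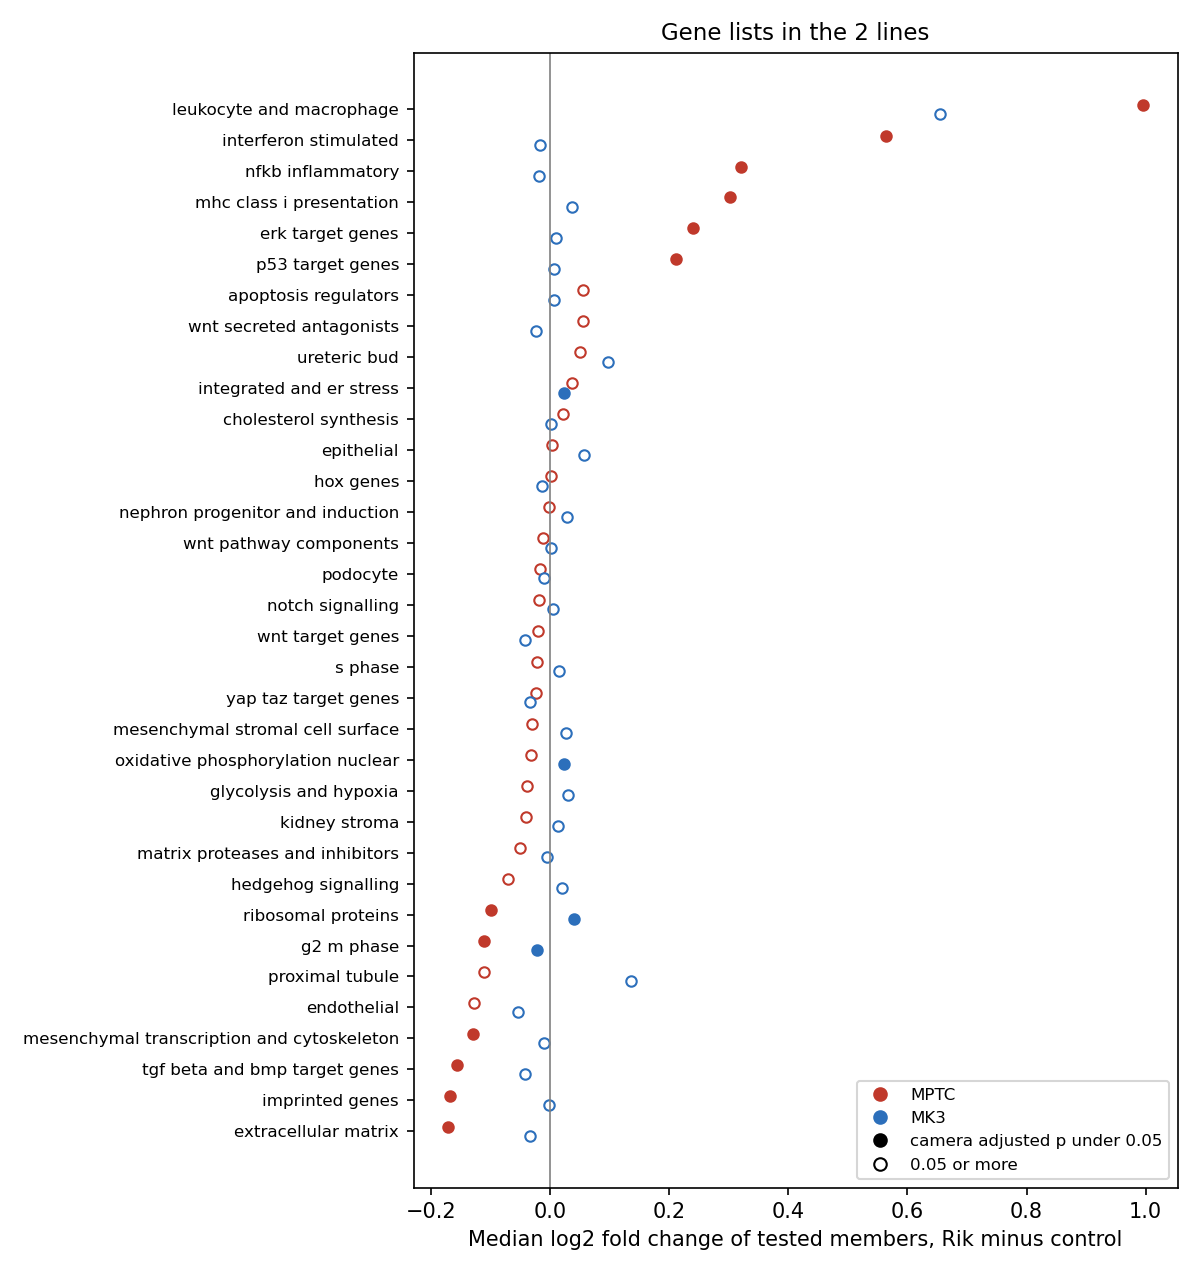
Median log2 fold change of tested members, Rik minus control (horizontal axis), for 34 gene lists (vertical axis) in MPTC (red) and MK3 (blue); filled points had a camera adjusted p under 0.05 with the preset correlation. The interferon-stimulated list stood at 0.56 in MPTC and -0.02 in MK3.

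The difference between the lines' responses was tested in the same fit. For interferon-stimulated genes the median difference of log2 fold changes, MPTC minus MK3, was 0.62, and 24 of 43 members differed, or 31 adjusted over the list alone (camera adjusted p = 3.58e-34, and adjusted p = 0.0958 with an estimated correlation). Ifi44 differed by 1.44, Dhx58 by 1.32 and Fbln1 by 1.52, and Ctnnb1 by -0.20 (edgeR adjusted p = 0.0131). The difference for Oas2, 1.30 (SE 0.45), was not called. Oas2 stood at 0.441 CPM in MK3 controls, against 1.79 CPM for Ifi44 and 5.83 CPM for Dhx58. Members at such low levels rest on few reads in MK3, so a change there can go unseen. For the Wnt targets 2 members differed, or 3 adjusted over the list alone (camera adjusted p = 0.232, and adjusted p = 0.393 with an estimated correlation). Over all genes, 449 differences were positive and 543 negative. The count of genes with different effect in the 2 lines, 992, was 1798, 477 and 532 without MPTC control replicates 1, 2 and 3 in turn and 561 without MPTC Rik replicate 1. It was 628, 616 and 647 without MK3 control replicate 2, control replicate 3 and Rik replicate 3, and 76 without MPTC control replicates 2 and 3 together. In that last fit Dhx58 and Fbln1 still differed, and Ifi44 (1.35) and Ctnnb1 (-0.14) did not. By edgeR 0 genes were called in both lines. DESeq2 called Sesn2 higher in both, and Ly6e lower in MK3 and higher in MPTC. Across genes, which are not independent replicates, the log2 fold changes of the lines had a Spearman correlation of 0.04 and a Pearson correlation of 0.08.

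The control libraries describe the lines themselves, for which line, medium and virus titre cannot be told apart. The nephric factors Pax2 and Pax8 averaged 60.8 and 44.6 CPM in MPTC controls and 0.301 and 0.125 CPM in MK3 controls, and Six4 7.42 and 62.4 CPM. Gatm, Anpep and Aqp1, known from the proximal tubule, had log2 fold changes, MPTC minus MK3, of -6.59 (SE 0.09), -5.77 (SE 0.09) and -3.22 (SE 0.12). In the epithelial list, Krt19 and Krt8 had -5.60 (SE 0.07) and -7.21 (SE 0.17) and Spint2, a protease inhibitor, 7.86 (SE 0.13). In the matrix list, Col6a1 and Npnt had -4.18 (SE 0.07) and -5.58 (SE 0.10) and Loxl1 8.47 (SE 0.15). Without MPTC control replicates 2 and 3, the log2 fold change of Krt8 between control lines was -9.93. In that fit Gatm, Anpep, Aqp1, Krt19 and Col6a1 also lay further from 0 and Npnt lay nearer to it. The higher and lower members in MPTC controls were 7 and 8 of 18 nephron genes, 5 and 3 of 11 proximal tubule genes, 10 and 7 of 18 epithelial genes and 10 and 22 of 33 matrix genes, with camera adjusted p of 0.921, 0.193, 0.881 and 0.00133. The median was positive and the test direction down for the proximal tubule and epithelial lists, and the matrix list had adjusted p = 0.279 with an estimated correlation. Interferon-stimulated genes were higher in MPTC controls for 41 of 43 members and lower for 1, with a median of 4.08 (camera adjusted p = 1.21e-39, and adjusted p = 0.192 with an estimated correlation). In total 10791 genes differed between the control lines by edgeR.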

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

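The tests of RNA from other cells below and the fit without MPTC control replicates 2 and 3 were chosen after the results were seen; the counts over other groupings of the libraries were planned. The change between control and Rik libraries differed between the lines for 992 genes, by a test of the difference itself. Among named genes the log2 difference, MPTC minus MK3, was 1.52 for Fbln1, 1.44 for Ifi44, 1.32 for Dhx58, 1.15 for Gramd1b, 1.04 for Lif, 0.82 for Ccl5, 0.65 for Cxcl1, 0.61 for Dusp6, 0.59 for Traf1, 0.50 for Ier3, 0.42 for Nlrc5, 0.39 for H2-K1, 0.36 for Ccn4, 0.36 for Fzd6, 0.33 for Fosl1, 0.28 for B2m and 0.22 for Gsk3b. It was -1.06 for Ptprn, -0.996 for Krt19, -0.85 for Cbr3, -0.73 for Tigit, -0.33 for Bub1b, -0.32 for Ube2c, -0.20 for Ctnnb1, -0.19 for Rpl27 and -0.15 for Tacc3. Lists that differed by camera with the preset correlation had median differences of 0.62 for interferon-stimulated genes, 0.27 for ERK targets, 0.25 for MHC class I presentation, 0.23 for NF-κB inflammatory genes and 0.19 for p53 targets. They were -0.39 for imprinted, -0.23 for epithelial, -0.17 for matrix, -0.15 for ribosomal protein, -0.10 for G2 and M phase and -0.062 for nuclear oxidative phosphorylation genes. With an estimated correlation 0 of these lists differed. Without MPTC control replicates 2 and 3, the epithelial (-0.11), matrix (0.00), imprinted (-0.54) and oxidative phosphorylation (-0.03) lists did not differ, and the ribosomal list differed by -0.06. Of the 26 genes, 8 then differed (Fbln1, Dhx58, Lif, Dusp6, H2-K1, Fzd6, B2m and Bub1b), while Gramd1b (0.63), Ptprn (-0.54), Krt19 (-0.62), Gsk3b (0.13) and the others did not. With each of the 12 libraries left out in turn, Tacc3 lost its call in 11 fits, Ccl5 in 9, Gsk3b in 7, Tigit in 7, Nlrc5 in 6, Cbr3 in 3 and Ccn4 in 1, and the oxidative phosphorylation list in 1, without MPTC Rik replicate 2. The imprinted difference was -0.15 without MK3 Rik replicate 1, the epithelial -0.15 without MK3 Rik replicate 3, the p53 0.12 without MPTC Rik replicate 1, and the NF-κB and oxidative phosphorylation ones 0.39 and -0.10 without MPTC control replicate 1.

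In MPTC the real grouping gave 2660 genes and the highest of the others 1, with 1 of 10 groupings as large as the real one. In MK3 the real grouping gave 0, the highest other 0, and 10 of 10 were as large. Between control lines the real grouping gave 10791 and the highest other 0, with 1 of 10 as large. In each case 10 groupings are too few for a share under 0.05. For the difference between lines 5 of 100 drawn groupings gave at least 992 genes and the highest gave 1496. The 12 draws that kept the real MPTC grouping gave 614 to 1496 and the other 88 at most 1, so the draws followed the MPTC grouping and do not decide on chance.

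Of 70 MPTC falls with an absolute log2 fold change over 1, 64 were in genes that a small share of MK3 RNA could shift by over 5%. Such genes made up 1055 of the 12683 tested. They were picked for a low level in MPTC against MK3. The 5% was the least shift for entry, so the possible shift of a member ranged from small to far larger. Being in this set therefore does not by itself show whether MK3 RNA gave a fall. Of 27 genes abundant in MK3 and low in MPTC, 96.3% lay higher in both control replicates 2 and 3 than in the other 4 MPTC libraries on average, against at most 25.9% for another pair, by a median 0.807% and 0.995% of the MK3 level, which is consistent with MK3 RNA in those replicates. For every other pair, the average it was set against held control replicate 2, 3 or both. Their lower shares therefore add no separate support. A first test, of the median share of the MK3 level, gave a ratio of 3.68 to the other libraries. This was short of the 5 set for it, and the test of pairs was chosen after that. Control replicate 1 lay above all 3 Rik libraries for 60.2% of all 118 called falls of such genes, against 93.2% of the 1274 other called falls, and among falls over 1 for 22 of 64 against 6 of 6. All were picked as falls in a fit that held control replicate 1, so neither these shares nor the 60% first set as a bar decide on lower expression in Rik cells, which stays open.

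Leukocyte and macrophage markers were higher in the Rik libraries than in MPTC control replicates 2 and 3, among them Lyz2 (0.408 and 0.442 against 19.1 to 22.9 CPM) and Tnf (0.102 and 0 against 27.6 to 31.1 CPM). Control replicate 1 goes against a rise caused by Rik. It held 1.08 times the summed marker level of the highest Rik library, with Lyz2 at 25.6 and Tnf at 37.5 CPM. It is 1 library, and control replicates 2 and 3 held 43.1 and 37.6 CPM in sum, so this does not settle the question. Over 12 detected markers, control replicate 1 stood at a median of 1.17 times the Rik mean (quartiles 0.881 and 1.37), which RNA of macrophages in these 4 libraries could give. Cd68 and Cd14 are also expressed in MK3, at 18.1 to 23.9 and 13.6 to 17.2 CPM, so they mark macrophages poorly here, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty stood at 0 CPM in control replicates 2 and 3 and at 0.055 to 0.889 CPM in the other 4 MPTC libraries. Neither the ratio nor these few Y-linked reads separate RNA of other cells from a difference between MPTC populations, which stays open.

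The rise of interferon-stimulated genes was weighed against both sources. Macrophage RNA is argued against by control replicate 1, which held the macrophage markers but lay under all 3 Rik libraries for 97.7% of the 43 members. Their summed level was 4270 CPM there and 6345 to 7188 CPM in the Rik libraries. This rests on 1 control library and repeats the lack of overlap given above. The members move together, so the 25% by chance for a single member gives no test over the list. MK3 RNA is argued against by the median log2 fold change of 0.616 without control replicates 2 and 3. An effect of Rik, a difference between cloned lines and a response to the infection itself were not tested and stay open.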

How the results depend on the processing

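The fits without MPTC control replicates 2 and 3 together, and without genes that MK3 RNA could shift, were chosen after seeing the data; the other alternatives were planned. Rik had no row, so its fold change could not be given under any setting. Leaving out 1 library gave 757 to 1374 higher and 870 to 1958 lower genes in MPTC, 0 to 1 higher in MK3, 477 to 1798 with a different effect and 10594 to 10902 between control lines. The lowest MPTC counts came without control replicate 2. Without MPTC control replicates 2 and 3, 238 were higher, 170 lower and 76 had a different effect; the lone control is assumed to vary like the other groups, and fewer samples lower the count. In that fit the median of leukocyte and macrophage markers reversed to -0.32. Without genes that MK3 RNA could shift, 2523 genes were called in MPTC. With an absolute log2 fold change over 1 the counts were 51 and 70 in MPTC, 78 for the difference and 3899 between control lines. In MK3, DESeq2 called 2 higher and 3 lower genes (1 higher in both lines), limma without a filter 2 and 2 with 2 lists, the replicate block 6 higher genes (Aplp1, Clip3, Kif5a, Sirpa, Spock2 and Srp54b, named after their values were seen; Kif5a stood at 23.2 CPM in Rik replicate 1 and at most 0.743 CPM in the other MK3 libraries) and each line alone 8 lists; the cause was not tested. Same-numbered libraries had correlations of their deviations of -0.04 to 0.04, so the numbers were not taken as pairs. With an estimated correlation 3 lists were called in MPTC, 0 in MK3 and 0 for the difference, and with fry in 1 direction 0 in MK3. Tests in 1 direction called Wnt targets under no setting run. Their medians were -0.06 to 0.02 in MPTC and -0.07 to -0.02 in MK3 when 1 library was left out. Without MPTC control replicates 2 and 3 the MPTC median was 0.08. The mixed test of fry called Wnt targets in MPTC (adjusted p = 1.01e-04) and for the difference (adjusted p = 0.00125). In MK3 it did not (adjusted p = 0.155). Of 813 values of named genes in MPTC, 785 kept their side of the threshold, 23 lost and 5 gained a call. Of 345 list values 325 kept theirs. Among the values that kept their side, 1 gene value and 3 list values, all uncalled, changed direction. At 1.69e+07 to 2.01e+07 counts per library, genes under 1 CPM rest on few reads.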

Other observations

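The values of Babam2, Itgb1 and the brain genes were chosen after seeing the data; the list and chromosome tests were planned. Further lists were lower in MPTC Rik libraries by camera with the preset correlation. Of 19 mesenchymal transcription and cytoskeleton genes, 6 fell and 0 rose (camera adjusted p = 0.00447, and adjusted p = 0.0774 with an estimated correlation), and of 24 TGF-β and BMP targets 7 fell and 1 rose (camera adjusted p = 0.0188, and adjusted p = 0.201 with an estimated correlation). Of 9 imprinted genes 4 fell and 1 rose (camera adjusted p = 0.0322, and adjusted p = 0.248 with an estimated correlation). Adjusted over the list alone, 9, 7 and 4 members were lower and 1, 1 and 1 higher. The TGF-β and BMP list was not called without MPTC Rik replicate 1 (-0.13), and the imprinted list without MK3 Rik replicate 1 (-0.17) or without control replicates 2 and 3. The imprinted median was -0.17 with all libraries and -0.38 without MPTC control replicate 1. Without control replicates 2 and 3 the medians of the TGF-β and BMP and the mesenchymal lists were -0.05 and -0.07, against -0.16 and -0.13 with all libraries, with 2 lower members each.

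Between the control lines, MHC class I genes were higher in MPTC for 15 of 18 members (camera adjusted p = 6.06e-09, and adjusted p = 0.256 with an estimated correlation). Genes of cholesterol synthesis were lower for 24 of 25 (camera adjusted p = 7.02e-09, and adjusted p = 0.192 with an estimated correlation) and genes of glycolysis and hypoxia for 26 of 33 (camera adjusted p = 4.38e-07, and adjusted p = 0.277 with an estimated correlation).

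Babam2, a subunit of a DNA repair complex, had the smallest p in MPTC and stood at 71.2 to 82.1 CPM in the control and 164 to 172 CPM in the Rik libraries. Itgb1 stood at 875 to 925 CPM in MPTC and 2.87 to 4.83 CPM in MK3 libraries. In MK3 Rik replicate 1, 14 of 16 genes known from brain had their highest level, with Mbp at 39.3 CPM against at most 0.981 CPM in the other MK3 libraries.

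Genes of chromosome 2 were lower in MPTC Rik libraries, with a median log2 fold change of -0.07 over 1005 genes, 221 lower and 49 higher, against 1171 lower and 1218 higher on the others. The median was -0.07 without control replicates 2 and 3 and 0.01 in MK3. By camera its adjusted p was 2.19e-04, and 0.00285 with an estimated correlation. Its mean level did not overlap between the 3 Rik and the 3 control libraries, as on most chromosomes. The 10 windows of 50 genes with the largest median in size were on it, at -0.145 to -0.119. Windows were set every 10 genes, so they can share genes. The median of chromosome 2 was the largest shift of a whole chromosome, 0.066 in size. It lay under the 0.1 set before the result was seen for a whole chromosome, with copy number as the source of the MPTC calls. A smaller difference in copy number of chromosome 2, or one in parts of it, stays open for its part of the calls.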
